A study of Mus musculus with 8 samples.

How the data were processed

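RNA was measured in sorted muscle stem cells from hindlimb muscle, 4 libraries from mice given PBS and 4 from mice given ketone bodies, with the group and number of each library taken from its labels. Per the labels' protocols, RNA was copied to cDNA from oligo(dT) primers with a low-input kit, sheared and amplified before sequencing, so polyadenylated transcripts are favoured and PCR copies count as separate reads. Per the submitters' processing notes, the tools used were Trim Galore, STAR, featureCounts, Subread and DESeq2 with the mouse build mm10, and their versions and settings are not given in the sources used here. The notes do not say whether counting used strand, so overlapping and antisense genes cannot be told apart. Near-identical copies such as Hspa1a and Hspa1b, and the ribosomal protein genes, are uncertain because reads can match several copies. Ly6a, Ly6c1, Ifit1, Oas2, H2-Aa, H2-Ab1 and Sult1a1 belong to gene families. How reads shared within a family were counted is not given in the sources used here.

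The table deposited by the authors holds a normalized signal per gene, namely read counts divided by 1 factor per library. In every library 100% of the values were whole multiples of the value of 1 read, within 0.001 of a read, so whole reads and depth could be recovered. Recovered depth ran from 19174005 to 36870537 reads per library, and 1 read was worth 0.638 to 1.39 normalized counts. Of 25239 rows, 2 carried a date in place of a gene symbol and were left out, and 6219 genes were at 0 in all libraries. Of the symbols, 96.5% were found in the GENCODE annotation of the same mouse build, which gave the coordinates. Mitochondrially encoded transcripts were not analysed here, so their list and their share could not be tested. Because the unit was a normalized signal, the limma test fixed for normalized values was the main test.

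Values were taken as log2(normalized count + 1), genes with a mean of at least 10 over the 8 libraries were kept (14022 genes), and limma 3.58.1 in R 4.3.3 was fitted without covariates (lmFit, eBayes with a trend and without robust estimation). Two-sided p-values were adjusted by Benjamini and Hochberg, with 0.05 as the threshold, and all adjusted p for genes are from limma unless another tool is named. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Lists were tested with camera of limma at a preset correlation of 0.01 for lists of at least 5 measured genes, and again with an estimated correlation and with fry, each adjusted over 32 lists. Fixed before the data were examined were 33 lists with 925 genes, of which 907 were in the table. They covered stem cell identity, myogenic, immediate early, replication, mitosis, p53, ketone metabolism, deacetylase, acetyltransferase, FOXO, NRF2, fatty acid oxidation, oxidative phosphorylation, mitochondrially encoded, glycolysis, ribosomal protein, mTORC1, autophagy, stress response, interferon, NF-kB, glucocorticoid, clock, cholesterol and matrix genes, markers of 7 other cell types, and nuclear RNAs. A gene could be in more than 1 list.

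The named genes followed a rule also fixed then: the 12 largest rises and 12 largest falls among genes that passed with no overlap between groups, leaving out predicted genes, the 4 members with the smallest p of each list that passed and the first of each other list, a fixed set of stem cell, cell cycle, p53 and ketone genes, and Nnt. Some genes under this rule are not reported here, and they stayed in every test and list. A gene at 0 in a whole group was given as a bound against a mean floor of 3 reads per library, and a gene with 1 to 3 reads in a group as a ratio with an exact 95% counting interval. Library measures were compared by two-sided exact permutation over 70 assignments, with a smallest possible p of 0.0286. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of 12.7 or more), so each counted once.

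On simulated data with 200 of 14022 genes changed in each of 5 runs, the main test recovered 8.8% of genes changed 1.5-fold, 46% at 2-fold, 80% at 4-fold and 90.4% at 8-fold. Of all calls 5.54% were false. In a separate simulation, run once with 1 shifted list, camera called that list and 0 of 20 unshifted lists. Simulated genes were drawn independently, so this does not check the list test for correlated genes (estimated correlation 0.31 for mitosis and 0.61 for endothelial genes). Far fewer genes were changed than the 3600 called in the data. Both simulated groups had the same dispersion, while the median SD of a gene was 0.20 in PBS and 0.40 in ketone. The recovery may therefore differ in the data. Alternatives were pseudocounts of 0.5 and 5, no filter and a filter at a mean of 50, TMM scaling, equal totals, quantile normalization, robust estimation, weights per library, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, other thresholds, lists without shared genes, the library number as a block, and leaving out each library in turn. On the recovered reads edgeR called 3597 genes and DESeq2 called 4179. Leaving out ketone libraries 1 and 2, and the endothelial list as a covariate, were alternatives chosen after seeing the data.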

Results

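RNA was sequenced from muscle stem cells of male mice given ketone bodies, the small acids the liver makes from fat during fasting, or phosphate-buffered saline (PBS) as the control. The cells were sorted from hindlimb muscle as positive for VCAM1 and negative for CD31, CD45 and Sca1. There were 4 PBS libraries and 4 ketone libraries, and the 1 comparison of the design asks which transcripts differ between the groups. Recovered reads per library were 29689632, 26284410, 26916025 and 19174005 for PBS and 36870537, 25465671, 26370898 and 26873992 for ketone. Depth did not separate the groups (two-sided exact permutation p = 0.486, adjusted p = 0.686 over 4 library measures). The other measures gave exact permutation p = 0.257 for the normalized total, 0.743 for the number of genes above 0 and 0.514 for the share of the 10 most abundant genes. The labels do not say that each library came from its own animal, so p-values measure the spread between these libraries, which may be partly technical. The strain entries read C57BL/6 for the PBS libraries and C57BL/7, C57BL/8 and C57BL/9 for the ketone libraries. Whether these entries name strains or are an entry error is not given in the sources used here. If they name strains, strain and treatment coincide, and no comparison here separates the 2.

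Cell cycle, cholesterol synthesis, stress response and matrix transcripts were lower in the ketone libraries, and endothelial and interferon response transcripts were higher. These lists passed with camera at a preset correlation of 0.01, and 0 of 32 lists passed with an estimated correlation (smallest adjusted p = 0.221, 5 lists at an unadjusted p below 0.05). Ccnd1, which encodes the G1 cyclin D1 (chromosome 7, 144929931 to 144939925), fell from 1682 ± 284 to 104 ± 49.6 normalized counts (means ± SD, n = 4 per group throughout). This was a log2 change of -4.13 ± 0.31 (SE). Psat1 of serine synthesis (chromosome 19, 15904678 to 15947337) fell by 3.11 and the collagen gene Col15a1 (chromosome 4, 47208161 to 47313167) fell by 2.78 on the log2 scale. Aqp1, a water channel of endothelial cells (chromosome 6, 55336432 to 55348555), rose by 3.04 ± 0.27, and Cd36, a fatty acid transporter (chromosome 5, 17781690 to 17888801), rose by 3.15 ± 0.19. Of 14022 genes tested, 3600 changed at an adjusted p below 0.05 by limma, 1800 higher and 1800 lower. Of these, 1154 were at least 2-fold higher and 628 at least 2-fold lower. In 3160 of the changed genes (87.8%) the groups did not overlap, and among all tested genes this held for 28.3% against 2.86% by chance. The median log2 change over tested genes was -0.01. Without PBS library 1 the count was 2356, and without PBS library 1 or 3 the genes lower numbered 1084 and 1192. With the mean of the endothelial list as a covariate, which lay at 8.69 to 9.10 in PBS and 10.43 to 11.74 in ketone and so follows the groups, 2 genes passed, Emp3 and Mthfd2, both lower. Over the 3600 genes the median size of the log2 change was 0.99 without it and 0.81 with it, and the median SE 0.22 and 0.65. With it 2872 of these genes had the same sign, and the log2 change of Ccnd1 was -3.58 ± 1.03, that of Col15a1 -3.10 ± 0.52, that of Psat1 -1.80 ± 0.70, that of Aqp1 0.60 ± 0.58 and that of Cd36 1.56 ± 0.44. Aqp1 is a member of the endothelial list, so its smaller change with the covariate is partly built in.

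Genes of the integrated stress response and unfolded protein response, which answer amino acid shortage and misfolded protein, fell as a group. Of 33 members 21 fell and 1 rose (23 and 4 adjusted over the list alone), with a median log2 change of -0.96. Stress response genes gave camera adjusted p = 1.06e-08, and adjusted p = 0.221 with an estimated correlation. Sesn2 went from 3872 ± 33.3 to 887 ± 184 normalized counts (log2 change -2.15, adjusted p = 1.87e-06). Mthfd2 of mitochondrial folate metabolism fell by 2.33 and Chac1, which degrades glutathione, fell by 1.92 on the log2 scale. In cholesterol synthesis 18 of 25 members fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -1.11. Cholesterol genes gave camera adjusted p = 6.86e-08, and adjusted p = 0.306 with an estimated correlation. With the endothelial covariate this list did not pass (median -0.60, adjusted p = 0.563). Cyp51 fell from 4823 ± 938 to 1468 ± 310.4 normalized counts, and its log2 change went from -1.71 to -0.61 with the covariate. The log2 changes of Sqle and Fdps were -1.53 and -1.84. Of the matrix and niche genes 20 of 32 fell and 4 rose (20 and 4 adjusted over the list alone), with a median of -0.85. Matrix genes gave camera adjusted p = 7.47e-08, and adjusted p = 0.221 with an estimated correlation. Col15a1 fell from 1772 ± 132 to 258 ± 35 normalized counts and Col5a3 from 6528 ± 1393 to 1137 ± 273. The basement membrane gene Nid2 fell by 1.75 and Col6a1 fell by 1.53 on the log2 scale.

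**Figure D1:**
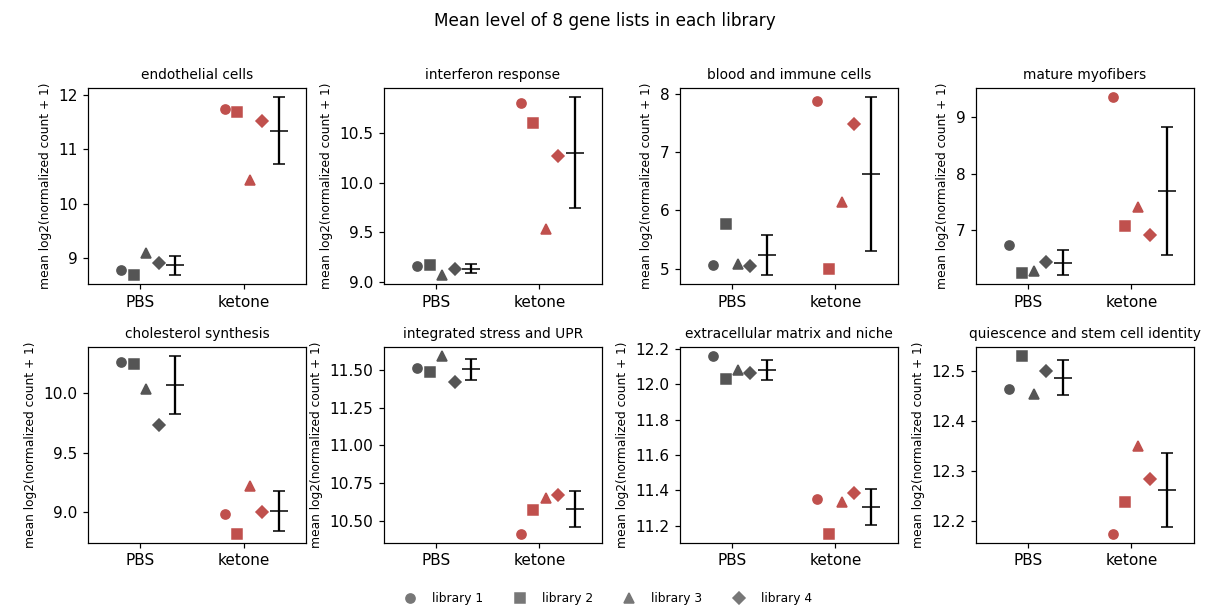
Mean log2(normalized count + 1) of the measured members of 8 gene lists in each library, with PBS in grey and ketone in red, one marker shape per library number, and the black line and bars for the mean ± SD of 4 libraries. The endothelial list lies between 8.69 and 9.10 in the PBS libraries, at 10.43 in ketone library 3 and between 11.53 and 11.74 in the other ketone libraries.

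Cell division transcripts were low in both groups and lower in the ketone libraries. Of 33 mitosis genes 16 fell and 0 rose (18 and 0 adjusted over the list alone), with a median log2 change of -1.52, also with Bub1 at its bound. Of the 18 mitosis genes with a mean of at least 50, 8 fell. Mitosis genes gave camera adjusted p = 6.86e-08, and adjusted p = 0.492 with an estimated correlation. Bub1 was listed at 0 in all 4 ketone libraries against 49.4 ± 28.2 in PBS, at least 17.8-fold lower for a mean floor of 3 reads per library. Cyclin A2 (Ccna2) fell from 170.1 ± 71.6 to 26.3 ± 14.1 normalized counts, Ect2 from 101 ± 36.2 to 17.4 ± 5.76 and Anln from 143 ± 57.4 to 19.1 ± 11.6. The proliferation marker Mki67 fell from 139 ± 73.9 to 17.4 ± 19.4 (adjusted p = 0.00877). Of 37 replication genes 12 fell and 1 rose, the same counts adjusted over the list alone, with a median of -0.34. Replication genes gave camera adjusted p = 0.00543, and adjusted p = 0.53 with an estimated correlation, and did not pass with the endothelial covariate (median -0.18, adjusted p = 0.492). Of them 6, 6 and 7 fell without PBS library 1, PBS library 4 and ketone library 2, in that order, and with equal totals 7. The log2 changes of E2f1, Chaf1b, Uhrf1 and Mcm2 were -1.97, -2.38, -2.71 and -1.15. Of 63 nuclear genes of oxidative phosphorylation 9 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.17. Oxidative phosphorylation genes gave camera adjusted p = 0.0138, and adjusted p = 0.864 with an estimated correlation, but adjusted p = 0.33 with fry. The number that fell was 3, 3, 4, 23 and 5 without PBS library 1, 3 and 4 and ketone library 1 and 4, in that order, and with library weights 24. The mean of this list was highest in ketone library 1, at 10.68, and 10.003 to 10.30 in the other ketone libraries, against 10.36 to 10.60 in PBS. Atp5b, Atp5a1 and Uqcrc1 changed by -0.73, -0.57 and -0.76 on the log2 scale. Sdha fell by 0.62 (adjusted p = 0.0159, but 0.052 and 0.0634 without PBS library 1 and 3). The call of this list was lost with quantile normalization (adjusted p = 0.251) and without PBS library 3 (adjusted p = 0.0513), ketone library 3 (adjusted p = 0.246) or ketone library 4 (adjusted p = 0.0935). The replication list lost its call without ketone libraries 1 and 2 (adjusted p = 0.0516), with a median of -0.44.

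Of 26 genes of FOXO and oxidative stress defence 10 rose and 1 fell (11 and 4 adjusted over the list alone), with a median log2 change of 0.55. FOXO genes gave camera adjusted p = 0.00863, and adjusted p = 0.306 with an estimated correlation, and did not pass with the endothelial covariate (median 0.30, adjusted p = 0.291). The transcription factor gene Klf15 rose from 431 ± 25.3 to 1393 ± 227 normalized counts and the mitophagy receptor gene Bnip3 from 392 ± 71.4 to 1177 ± 158. Gadd45g and Txnip rose by 1.14 and 0.92 on the log2 scale. Glucocorticoid targets gave 7 of 19 higher and 0 lower (9 and 1 adjusted over the list alone), with a median of 0.48. Glucocorticoid genes gave camera adjusted p = 0.00902, and adjusted p = 0.53 with an estimated correlation. Without ketone libraries 1 and 2 the camera adjusted p of this list was 0.0516. Sult1a1, Tsc22d3, Lcn2 and Dusp1 rose by 3.27, 1.34, 2.86 and 0.75 on the log2 scale. Of 38 interferon response genes 24 rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 0.93. Interferon genes gave camera adjusted p = 6.92e-09, and adjusted p = 0.552 with an estimated correlation. With the endothelial covariate the interferon list passed as lower (median -0.90, adjusted p = 0.000197), and Ifit1 was at -0.11 ± 0.54. Ifit1 rose from 592 ± 68.6 to 5151 ± 2228 normalized counts. Rsad2, Ifit2 and Isg15 rose by 2.36, 2.18 and 2.15 on the log2 scale. The interferon list mean was 9.53 in ketone library 3 and between 10.27 and 10.81 in the other ketone libraries, against 9.07 to 9.17 in PBS. The endothelial transcripts were lowest in the same ketone library.

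For 77 ribosomal protein genes the median log2 change was 0.30. Ribosomal protein genes gave camera adjusted p = 0.00181, and adjusted p = 0.864 with an estimated correlation. Of these members 1 rose and 0 fell, and 0 passed in either direction adjusted over the list alone. The number that rose was 0 with no filter or TMM scaling, 6 with the replicate block, 10 with DESeq2, 11 without ketone library 3, 10 without ketone library 4 and 0 without any other 1 library. Their mean was 10.94 and 11.11 in ketone libraries 1 and 2 and 10.22 and 10.21 in ketone libraries 3 and 4, against 10.21 to 10.47 in PBS. Without ketone library 2 the camera adjusted p of the list was 0.148, with library weights 0.208 and by fry 0.395. With the endothelial covariate the list passed as lower (median -0.82, adjusted p = 1.7e-07), and without ketone libraries 1 and 2 its median turned to -0.11. Rps24, the member that passed, rose by 0.63 (adjusted p = 0.0461). Its adjusted p was 0.137, 0.0592, 0.0668 and 0.13 without PBS library 1, 2, 3 and 4 and 0.0914 and 0.108 without ketone library 1 and 2. With no filter it was 0.064 and with TMM scaling 0.0507. Rps19, Rpl14 and Rpl9 did not pass, with log2 changes of 0.54, 0.58 and 0.58 (adjusted p = 0.0681, 0.0723 and 0.0732). With DESeq2 all 3 passed (adjusted p = 0.0238, 0.0208 and 0.0282), and Rpl14 also with the replicate block (adjusted p = 0.0375) and quantile normalization (adjusted p = 0.0486). They passed without ketone library 3 (adjusted p = 0.0406, 0.0319 and 0.0177). Rps19 and Rpl14 also passed without ketone library 4 (adjusted p = 0.021 and 0.0265). Ribosomal protein genes have near-identical pseudogenes, so these values are uncertain. The ribosomal RNA precursor Rn45s stood at 363069 and 396262 normalized counts in ketone libraries 1 and 2 and at 62561 and 60108 in ketone libraries 3 and 4, against a PBS mean of 94705 ± 17724. Lars2 split the ketone libraries in the same way, with 466606 and 578264 against 85816 and 89958. Malat1 did not, with 472394 in ketone library 2 and 171380 to 187013 in the other ketone libraries. These 3 genes were chosen after the data were seen. Without ketone libraries 1 and 2, 4682 genes changed, 3100 of them among the 3600 and in the same direction. Of the nuclear and long non-coding RNAs 1 of 9 rose, Neat1 by 1.65 on the log2 scale, and 1 fell (camera adjusted p = 0.436, 1 and 1 adjusted over the list alone). Their mean was 11.79 in ketone library 2 and 10.53 to 11.03 in the other ketone libraries, against 10.58 to 10.73 in PBS.

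Markers of other cell types were higher in the ketone libraries for 5 of 7 lists. All 17 endothelial genes rose, also adjusted over the list alone, with a median log2 change of 2.61. Endothelial genes gave camera adjusted p = 1.56e-12, and adjusted p = 0.306 with an estimated correlation. Aqp1 rose from 3264 ± 732 to 28175 ± 10959 normalized counts and the VEGF receptor gene Flt1 from 512 ± 74.7 to 5014 ± 1787. Ptprb and Ly6c1 rose by 2.75 and 3.56 on the log2 scale. Pecam1, which encodes the sort marker CD31, rose from 733 ± 118 to 4233 ± 1506 and had its lowest ketone value in ketone library 3, at 2130.4. Ly6a, which encodes Sca1 and stands in the fibro-adipogenic list, rose from 535 ± 29.7 to 4907 ± 1742. Ptprc, which encodes CD45, was at 20.3 ± 5.49 and 94.1 ± 136 and did not pass (adjusted p = 0.217), with 299 in ketone library 1 and 21.1 to 30.1 in the others. Of the smooth muscle and pericyte genes 11 of 18 rose and 2 fell (11 and 4 adjusted over the list alone). With no filter or with equal totals 1 of them fell. Smooth muscle genes gave camera adjusted p = 0.00863, and adjusted p = 0.552 with an estimated correlation. Rgs5, Kcnj8 and Mustn1 rose by 2.11, 1.71 and 2.60, and Notch3, also a stem cell gene, fell by 1.68 on the log2 scale. Of the Schwann cell genes 8 of 14 rose and 2 fell, the same adjusted over the list alone. Schwann cell genes gave camera adjusted p = 0.00925, and adjusted p = 0.552 with an estimated correlation. The myelin genes Mbp and Prx rose by 2.36 and 2.04. In blood and immune cells 8 of 20 rose and 0 fell, the same adjusted over the list alone. Blood and immune genes gave camera adjusted p = 0.00147, and adjusted p = 0.637 with an estimated correlation, but adjusted p = 0.102 with fry. Their mean was 4.99 in ketone library 2, below every PBS library (5.06 to 5.76), and 7.88, 6.15 and 7.48 in ketone libraries 1, 3 and 4. Cd79a, H2-Aa, H2-Ab1 and Laptm5 rose by 2.42, 1.85, 1.96 and 1.61. Of the myofiber genes 14 of 25 rose and 2 fell (15 and 2 adjusted over the list alone). Myofiber genes gave camera adjusted p = 0.00736, and adjusted p = 0.796 with an estimated correlation, but adjusted p = 0.21 with fry. Their mean was 9.35 in ketone library 1 and 6.92 to 7.41 in the other ketone libraries, against 6.25 to 6.74 in PBS. Myh4 and Mb rose by 2.99 and 3.49, while Actn3 fell from 7321 ± 1216 to 1876 ± 945 normalized counts and Pygm from 2547 ± 364 to 763 ± 288. Among fibro-adipogenic genes, 6 of 16 measured members rose and 3 fell (7 and 5 adjusted over the list alone). Fibro-adipogenic genes gave camera adjusted p = 0.169, and adjusted p = 0.0485 on the reads with edgeR. Of them 1 fell without PBS library 3 and 5 without ketone library 1. Among tenocyte genes, 5 of 12 measured members rose and 1 fell (6 and 1 adjusted over the list alone). Tenocyte genes gave camera adjusted p = 0.169. Only 3 tenocyte genes rose without PBS library 1 or 2 or ketone library 1 or 4. Fmod rose by 2.07 on the log2 scale.

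Among quiescence and stem cell identity genes, 6 of 38 measured members rose and 10 fell (6 and 11 adjusted over the list alone). Identity genes gave camera adjusted p = 0.185, but adjusted p = 0.0134 with fry and 0.0353 on the reads with edgeR, in both lower. Pax7, the transcription factor that marks these cells, was at 2125 ± 301 and 1792 ± 215 normalized counts, a log2 change of -0.24 ± 0.15 that did not pass (adjusted p = 0.265). Col5a3 and the calcitonin receptor gene Calcr fell, Calcr from 8352 ± 492 to 4604 ± 1566 (adjusted p = 0.00634), and the Notch target Hes1 rose from 2377 ± 252 to 3822 ± 665 (adjusted p = 0.00637). Vcam1, the marker selected for in the sort, fell by 0.85 on the log2 scale (adjusted p = 0.0206). Its adjusted p was 0.0508, 0.0549, 0.0645 and 0.0501 without PBS library 1, 2, 3 and ketone library 2. Cd34 rose by 0.45 (adjusted p = 0.045). Its call was lost without any 1 of the PBS libraries 1 to 4 (adjusted p = 0.114, 0.0726, 0.111 and 0.129) or without ketone library 3 or 4 (adjusted p = 0.0864 and 0.113). Cd34 also lost its call with the replicate block (adjusted p = 0.0698), TMM scaling (adjusted p = 0.0536) and no filter (adjusted p = 0.0723). Myf5 was at -0.39 (adjusted p = 0.119, and 0.0286 without ketone library 3 and 0.0473 with library weights). Notch1, Heyl, Cdkn1b, Cdkn1c and Foxo3 were at -0.26, 0.07, 0.18, 0.10 and -0.13 and did not pass (adjusted p = 0.22, 0.804, 0.601, 0.778 and 0.78). Among myogenic genes, 8 of 25 measured members rose and 7 fell (9 and 7 adjusted over the list alone). Myogenic genes gave camera adjusted p = 0.918. With DESeq2 on the reads 3 myogenic genes rose and 7 fell. Their median of 0.07 and mean of -0.07 differed in sign. The acetylcholine receptor gene Chrna1 fell from 5978 ± 889 to 939 ± 271, and Myod1 from 35149 ± 4803 to 20496 ± 6362 (adjusted p = 0.0135). Myog, the myogenin gene, fell from 951 ± 469 to 112 ± 91.8 (adjusted p = 0.0199). Myog was listed at 0 in ketone library 4 and lost its call without PBS library 2 or 4 (adjusted p = 0.06 and 0.0569) and with robust estimation (adjusted p = 0.126).

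**Figure D2:**
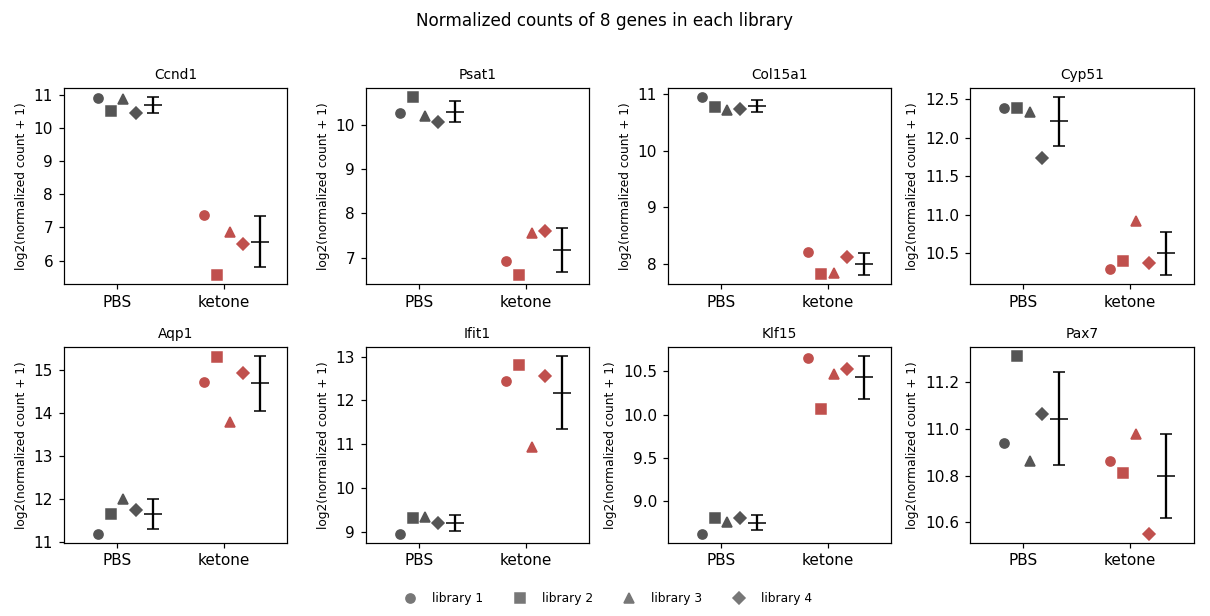
Log2(normalized count + 1) of 8 genes in each library, with PBS in grey and ketone in red, one marker shape per library number, and the black line and bars for the mean ± SD of 4 libraries. Ccnd1, Psat1, Col15a1 and Cyp51 are lower in every ketone library than in any PBS library, Aqp1, Ifit1 and Klf15 are higher, and Pax7 overlaps.

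Among genes of ketone body transport and metabolism, 0 of 12 measured members rose and 3 fell (0 and 3 adjusted over the list alone). Ketone metabolism genes gave camera adjusted p = 0.272, but adjusted p = 0.0337 with fry, lower. Aacs fell from 1219 ± 71.4 to 749 ± 90.9 normalized counts. The transporter gene Slc16a1 and the enzyme gene Oxct1 were at -0.08 and -0.30 on the log2 scale and did not pass (adjusted p = 0.837 and 0.228). Bdh1 lay below the filter at 4.32 ± 5.02 and 11.2 ± 13.5 normalized counts. Among deacetylase and sirtuin genes, 0 of 22 measured members rose and 3 fell (0 and 3 adjusted over the list alone). Deacetylase genes gave camera adjusted p = 0.858. Of them 6 fell without ketone library 2. Hdac2 fell by 0.68 on the log2 scale, and Hdac1 was at 0.09 and did not pass (adjusted p = 0.707). Among acetyltransferase and acetyl-CoA genes, 1 of 17 measured members rose and 1 fell (1 and 1 adjusted over the list alone). With equal totals 3 rose and 0 fell. Acetyltransferase genes gave camera adjusted p = 0.858. Acss1 rose by 1.68. Of the p53 targets, 7 of 42 measured members rose and 6 fell (7 and 6 adjusted over the list alone). The p53 target genes gave camera adjusted p = 0.778. Of these targets 3 fell without PBS library 1, 2 or 3. Trp53 itself fell from 2349 ± 82.1 to 1615 ± 290.5 (adjusted p = 0.018, and 0.0552 and 0.051 without PBS library 1 and 4). Cdkn1a, a target of p53 that stops the cell cycle, rose from 10263 ± 489 to 16174 ± 4322 (adjusted p = 0.0217, and 0.0737, 0.0512 and 0.0605 without PBS library 1, 3 and 4). Mdm2, another target, was at -0.18 and did not pass (adjusted p = 0.403). Nnt, which differs between substrains of C57BL/6, fell from 565 ± 63.8 to 352 ± 94.8 (adjusted p = 0.0246, and 0.0771 and 0.0825 without PBS library 1 and 3).

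Among immediate early and dissociation genes, 8 of 36 measured members rose and 6 fell (8 and 7 adjusted over the list alone). Immediate early genes gave camera adjusted p = 0.778, but adjusted p = 0.0192 with the endothelial covariate, higher (median 0.55). The chaperone gene Hsph1 fell from 70532 ± 6076 to 19968 ± 1852 normalized counts. Of the NRF2 targets, 5 of 26 measured members rose and 3 fell (5 and 3 adjusted over the list alone). NRF2 target genes gave camera adjusted p = 0.965. The number that rose was 2, 3, 2, 2 and 3 without PBS library 1, 2, 3 and 4 and ketone library 4, in that order, and 5 fell without ketone library 1. Taldo1 fell by 0.84 on the log2 scale. In fatty acid oxidation, 4 of 32 measured members rose and 7 fell (4 and 7 adjusted over the list alone). Fatty acid oxidation genes gave camera adjusted p = 0.858. Leaving out PBS library 1, 2, 3 or 4 or ketone library 2 gave 1, 3, 2, 2 and 3 that fell, in that order, and 2 rose without PBS library 2 or ketone library 4. More rose than fell with equal totals (5 and 2) and without PBS library 1 (3 and 1), PBS library 3 (3 and 2), PBS library 4 (3 and 2) or ketone library 2 (4 and 3). Cd36 rose from 1405 ± 113 to 12815 ± 3278. Its lowest ketone value, 8033, was in ketone library 3, the library with the lowest endothelial list mean. Whether this rise took place in the stem cells was not tested. In glycolysis, 4 of 25 measured members rose and 6 fell (5 and 6 adjusted over the list alone). Glycolysis genes gave camera adjusted p = 0.841. Only 2 fell without PBS library 1, 3 or 4. Pfkfb3 rose by 1.12. In mTORC1 and translation control, 0 of 31 measured members rose and 7 fell (0 and 6 adjusted over the list alone). The mTORC1 genes gave camera adjusted p = 0.261, but adjusted p = 0.0337 with fry, lower. The number that fell was 4 without PBS library 1 or 3. The amino acid transporter gene Slc7a5 fell by 1.55. In autophagy and lysosome, 5 of 39 measured members rose and 1 fell (4 and 1 adjusted over the list alone). Autophagy genes gave camera adjusted p = 0.684. Leaving out PBS library 1 or 2 gave 2 and 3 that rose. Map1lc3b rose from 6440 ± 678 to 14159 ± 1142. Of the NF-kB and cytokine genes, 8 of 27 measured members rose and 1 fell (9 and 1 adjusted over the list alone). NF-kB genes gave camera adjusted p = 0.215, but adjusted p = 0.0344 with library weights and 0.0223 without ketone libraries 1 and 2, both higher. Of them 5 rose without PBS library 1, and 4, 2 and 4 fell without ketone library 2, 3 and 4, in that order. Il6ra rose by 2.51. Of the clock genes, 5 of 20 measured members rose and 2 fell (6 and 2 adjusted over the list alone). Clock genes gave camera adjusted p = 0.378, but adjusted p = 0.0164 with the endothelial covariate, higher (median 0.84). The median and the mean of the log2 changes differed in sign for the NRF2, fatty acid oxidation and glycolysis lists (0.06 and -0.01, -0.05 and 0.07, -0.14 and 0.06). For the deacetylase list the median of 0.08 and the mean of 0.02 were positive where camera ranked the list lower.

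Among the genes with the largest rise were Cyp1a1, a target of the aryl hydrocarbon receptor, from 3.32 ± 4.96 to 105 ± 47 normalized counts, and Fam107a from 27.2 ± 17.7 to 647 ± 358. The NADPH oxidase gene Nox4 rose from 10.6 ± 2.34 to 200 ± 74 and the neurotensin gene Nts from 5.71 ± 4.37 to 109 ± 18.5. Ms4a1 and Cd40, both expressed in B cells, rose from 1.57 ± 2 to 85.7 ± 88.3 and from 1.84 ± 3.68 to 51.7 ± 15.8. Lao1 rose from 2.3 ± 2.35 to 65.1 ± 39.8 and the interferon target Oas2 from 11.3 ± 10.1 to 135 ± 70. With 1 to 3 reads over the PBS libraries, Mctp2 was higher by 78.1-fold (95% counting interval 21.3 to 650), Corin by 107-fold (95% counting interval 18.9 to 4258), Slco1a5 by 61-fold (95% counting interval 16.6 to 509) and Srarp by 38.7-fold (95% counting interval 13 to 190.1). The largest falls included Iqgap3, the mitotic kinase gene Melk and Rgs8, listed at 0 in all ketone libraries against 59.3 ± 39.4, 50 ± 25.9 and 24.7 ± 8.06 in PBS. They were at least 21.3-fold, 18-fold and 8.89-fold lower for a mean floor of 3 reads per library. Chrng, of the fetal acetylcholine receptor, and Hkdc1, with 2 and 3 reads over the ketone libraries, were lower by 132-fold (95% counting interval 36.2 to 1099) and 71-fold (95% counting interval 23.9 to 348). Cacna2d4 fell from 119 ± 37.8 to 5.49 ± 7.11, Kntc1 from 64.3 ± 25.5 to 2.49 ± 4.98 and Pbk from 73.3 ± 28.5 to 2.6 ± 3.15. Il1rl1 fell from 63.6 ± 41.3 to 1.5 ± 1.73, Mgam from 293 ± 69.5 to 17.6 ± 15 and Mymk, the myoblast fusion gene, from 143 ± 90.2 to 11.2 ± 13.9. The adjusted p of these genes and Bub1 lay between 6.91e-06 and 0.00529. Intervals and floors cover counting error only.

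**Figure D3:**
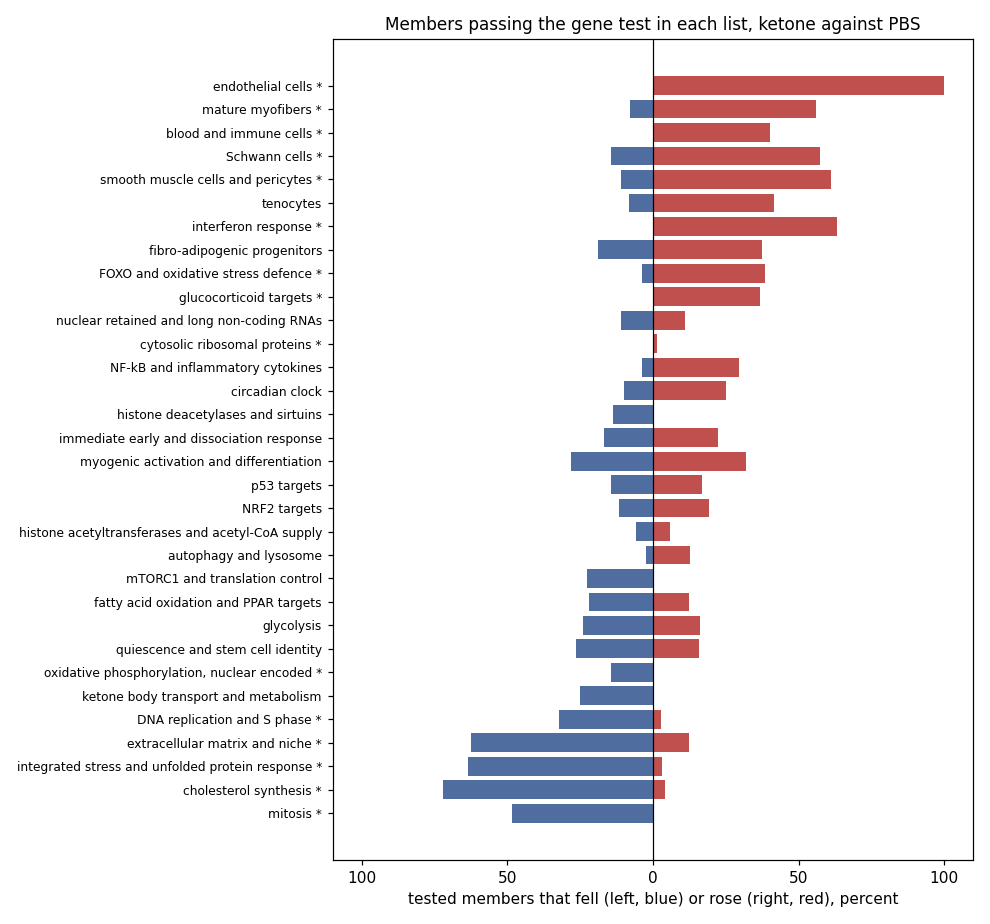
Share of the tested members of each of 32 gene lists that fell (blue, left) or rose (red, right) in ketone against PBS, in percent, with lists in order of their median log2 change and an asterisk where camera with the preset correlation passed. All 17 endothelial genes rose, and 21 of 33 stress response genes fell.

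Of 32 lists tested, 15 passed with camera at a preset correlation of 0.01, 9 higher and 6 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.221), with 5 lists at an unadjusted p below 0.05. With the directional test of fry 14 passed, 11 of them among the 15. Not passing with fry were oxidative phosphorylation, ribosomal proteins, blood and immune cells and myofibers (adjusted p = 0.33, 0.395, 0.102 and 0.21). Passing with fry but not among the 15 were stem cell identity, ketone metabolism and mTORC1 (adjusted p = 0.0134, 0.0337 and 0.0337), each lower. Stem cell identity also passed with camera on the reads with edgeR (adjusted p = 0.0353). With the endothelial covariate 8 lists passed. The covariate did not overlap between the groups (8.69 to 9.10 in PBS and 10.43 to 11.74 in ketone), so calls kept or lost under it are no firm evidence. It is the mean of the endothelial list itself, so the lost call of that list was fixed in advance. Of the 15, mitosis (median -1.01, adjusted p = 0.0153), stress response (median -0.84, adjusted p = 0.000453) and matrix (median -0.49, adjusted p = 0.000743) kept their call and direction. Oxidative phosphorylation also passed as lower (adjusted p = 8.1e-12), but its median moved from -0.17 to -0.99. Interferon and ribosomal proteins passed in the opposite direction, and clock and immediate early genes passed only here. The other lists lost their call: replication (median -0.18, adjusted p = 0.492), cholesterol (median -0.60, adjusted p = 0.563), FOXO (median 0.30, adjusted p = 0.291), glucocorticoid targets (median 0.0467, adjusted p = 0.83), endothelial (median -0.09, adjusted p = 0.83), smooth muscle (median 0.11, adjusted p = 0.83), Schwann cells (median 0.69, adjusted p = 0.444), blood and immune (median 1.03, adjusted p = 0.83) and myofibers (median 0.18, adjusted p = 0.998). Of the 35 splits of the 8 libraries, the real one included, 3 gave at least 15 lists.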

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

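Apart from the counts over splits of the libraries, which were planned, the tests in this part were chosen after the results they bear on had been seen in part. All 17 endothelial markers rose although the sort excluded CD31, with mean ketone levels of 28175 for Aqp1, 7736 for Ly6c1, 5014 for Flt1 and 4233 for Pecam1. The authors' scaling is argued against, since all 17 of 17 rose under TMM, equal totals and quantile scaling. RNA from endothelial cells would set all markers at 1 ratio, and this ratio was not tested. In 16 of the 17 ketone library 3 was the lowest of the ketone libraries, as a source smaller in that library would give. That library was picked because it was lowest in Pecam1, which is 1 of the 17. Its excess over PBS was low for risen genes in general, with a median of 62.5% of that in the other ketone libraries, against 32.4% for these markers. The markers are not independent of each other, so the pattern may equally come from a joint rise of these genes in the sorted cells, which was not tested. Sort purity was not measured here.

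The mitosis, replication, oxidative phosphorylation, cholesterol, stress response and matrix lists were lower. For the mitosis, cholesterol, stress response and matrix lists the median log2 change of their 123 members was -1.20 (95% bootstrap interval -1.29 to -0.93). This interval lay below that of 38 stem cell identity genes, with a median of -0.17 (-0.36 to 0.10). Dilution of stem cell RNA by other cells alone would lower the identity genes at least as much. These values thus argue against dilution as the whole cause for these lists, and a part for it stays open. The lists were taken because they were lower, and genes are not independent. The identity list is also not limited to stem cells, since Des and Notch3 are in the smooth muscle list too. RNA of other cells could raise some of its genes and hide dilution. Pax7 and Myf5 are in no list of another cell type. Their log2 changes were -0.24 ± 0.15 and -0.39 ± 0.17 (SE), above the interval of the members. Calcr, also in no such list, was lower, at -0.92 ± 0.21. For the 100 members of the replication and oxidative phosphorylation lists dilution stays open as the whole cause, with a median of -0.20 (-0.37 to -0.11). The features of ketone libraries 1 and 2 are argued against, since 94.8% of the 96 members of the 6 lists that fell still passed without them, while the replication list lost its call (adjusted p = 0.0516) with a median of -0.44 against -0.34 with them. Weaker stress during isolation stays open: the median change of 30 immediate early genes without chaperones was 0.22, with 8 higher and 1 lower, while 5 of 6 chaperone genes in the same list fell, and so does an effect of the treatment on the cells.

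The interferon genes rose with the endothelial markers. In the interferon genes that rose, the excess over PBS in ketone library 3 was a median of 26.9% of that in the other 3 ketone libraries, close to the 32.4% of the endothelial markers, against 62.5% (quartiles 35.4% to 104%) over all 1800 genes that rose. This leaves RNA from endothelial or other cells as a candidate source, but it rests on 1 library. The quartiles of the interferon genes were 4.82% to 37.8%. Myogenic genes that rose gave 27.7% and NRF2 targets 33.0%. Other cell type lists gave 35.2% (smooth muscle), 39.4% (tenocytes), 41.4% (myofibers), 41.5% (blood and immune), 43.6% (Schwann cells) and 77.4% (fibro-adipogenic). A low value is therefore not specific to endothelial cells. The myogenic list shares genes with the myofiber list. Its mean was 9.31 in ketone library 1 and 7.95, 8.23 and 7.54 in ketone libraries 2, 3 and 4. A low value can thus also go with a high ketone library 1. Without ketone libraries 1 and 2, 75% of the interferon genes that rose still passed (18 of 24), too few to exclude a part for these libraries and too many to blame them alone. An interferon response of the stem cells was not tested.

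For 1 of 35 splits of the 8 libraries, the real one, as many genes passed as the 3600 observed, and the highest other split gave 5. Every other split mixed the groups, so the group difference widened the spread within its parts and lowered its count. The real split being the highest of 35 is the strongest outcome possible with 8 libraries. It does not exclude chance for the number of genes, nor does it say what separated the groups. For the number of lists chance cannot be excluded either: 3 of 35 splits gave at least 15, and the highest other value was 15. The other splits with 15 mixed 3 libraries of 1 group with 1 of the other. They keep part of the group difference and are no clean measure of chance.

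A gap between 1 library and the rest of its group, as a ratio to the range of the group above Dixon's 95% critical value, was found in 17 of 296 groups, leaving out those with 3 or 4 libraries at 0, where chance gives about 1 in 20 and so 14.8. Ketone library 1 had more reads, 36870537 against 25465671 to 26873992 (ratio 0.877). Ketone library 3 had the lowest endothelial list mean (10.43 against 11.53 to 11.74, ratio 0.836) and PBS library 2 the highest blood and immune list mean (5.76 against 5.06 to 5.08, ratio 0.964). On the log2(normalized count + 1) scale, ketone library 3 stood apart for Hdac2 (11.13 against 10.88 to 10.90, ratio 0.943), Cyp51 (10.92 against 10.30 to 10.40, ratio 0.836), Ly6a (11.18 against 12.44 to 12.58, ratio 0.901) and Ly6c1 (12.001 against 13.09 to 13.19, ratio 0.918). Ketone library 1 stood apart for Chac1 (7.65 against 8.04 to 8.08, ratio 0.89), Cd79a (8.36 against 7.20 to 7.27, ratio 0.941) and Slc16a1 (11.76 against 12.95 to 13.12, ratio 0.876), while ketone library 4 did so for Myog (0.00 against 6.56 to 7.79, ratio 0.842). Among PBS libraries, library 2 stood apart for Rgs8 (5.24 against 4.37 to 4.49, ratio 0.859), Uqcrc1 (11.74 against 12.18 to 12.25, ratio 0.865) and Actn3 (12.43 against 12.91 to 12.99, ratio 0.854), library 3 for Rgs5 (10.72 against 10.97 to 11.01, ratio 0.856) and library 4 for Mgam (7.57 against 8.31 to 8.38, ratio 0.906) and Cyp51 (11.74 against 12.33 to 12.39, ratio 0.916).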

How the results depend on the processing

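The alternatives without ketone libraries 1 and 2 and with the endothelial covariate were chosen after seeing the data. Leaving out 1 library in turn gave 2356 to 4070 changed genes, 1272 to 1943 higher, 1084 to 2127 lower and 14 to 15 lists, with fewer libraries in each fit. A log2 change of at least 1 in size kept 1782 genes. The estimated correlation left 0 lists. With the endothelial covariate, which rises with the groups, 2 genes changed, 0 higher and 2 lower by limma, with 1587 genes at an unadjusted p below 0.05 and 766 of them higher. No other tool was run with it, and 8 lists passed. The median SE over the 3600 genes went from 0.22 to 0.65 and the median size of the log2 change from 0.99 to 0.81, and 1284 of them were at least as large in the same direction. Under it the log2 change turned to 0.69 for Cacna2d4, 0.84 for Kntc1, -0.57 for Rps24, -0.11 for Ifit1, -0.14 for Isg15, 0.18 for Calcr and 0.32 for Nnt. The test direction of lists turned for ribosomal proteins (median -0.82, which passed as lower with adjusted p = 1.7e-07, and -0.11 without ketone libraries 1 and 2), interferon response (median -0.90, which passed as lower with adjusted p = 0.000197) and, without passing, glucocorticoid targets (median 0.0467), myofibers (median 0.18) and smooth muscle (median 0.11). The cause of these turns was not tested. Over all alternatives, values of named genes were on the same side of the threshold 2385 times (25 of them with the opposite sign, in genes that passed in neither), lost the call 130 times (94 of them with the covariate), gained it 12 times and turned 7 times. For lists these counts were 720 (22 in the opposite direction), 33, 9 and 6. The share of higher genes among those that changed was 50% as reported and 57.7% with equal totals. Same-numbered libraries did not deviate together (r across genes 0.11, -0.01, 0.00 and -0.06 for numbers 1 to 4, and genes are not replicates). The replicate block gave 3595 changed genes, 1781 higher and 1814 lower, and 15 lists. Depth sets the floor: 1 read was worth 0.638 to 1.39 normalized counts, so genes at 0 have bounds only.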

Other observations

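The genes and lists in this part were chosen after their values were seen, so their p-values are no independent evidence. Heat shock chaperones were abundant and lower in the ketone libraries: 23 of 26 measured members fell and 0 rose, with a median log2 change of -0.99. Dnajb1, a partner of HSP70, went from 221572 ± 33278 to 72989.5 ± 27867 normalized counts (log2 change -1.66, adjusted p = 0.000417). Serpinh1, a collagen chaperone, went from 49716 ± 5477 to 9979 ± 2195 (log2 change -2.33, adjusted p = 2.09e-06) and Dnaja4 from 22416 ± 2361 to 4338 ± 695 (log2 change -2.38, adjusted p = 9.33e-07). Hspa1a and Hspa1b, near-identical copies whose separate values are uncertain, stood at 474317 and 513875 in PBS and 235918 and 257705 in ketone. Camera gave adjusted p = 2.78e-14 for the chaperones, adjusted over the 4 lists of this part, and adjusted p = 0.000972 with an estimated correlation. The immediate early genes Fos, Egr1, Jun, Atf3 and Nr4a1 were at -0.02, -0.11, -0.28, 0.23 and -0.42 on the log2 scale and did not pass (adjusted p = 0.949, 0.778, 0.328, 0.355 and 0.132), and Ier3 rose by 1.02 (adjusted p = 0.00172).

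In serine and one-carbon synthesis, which shares Psat1, Phgdh, Shmt2 and Mthfd2 with the stress response list, 7 of 14 measured members fell and 0 rose (camera adjusted p = 0.000152, and adjusted p = 0.0357 with an estimated correlation). Phgdh, the first enzyme of the pathway, fell from 451 ± 89 to 54.6 ± 29.3 normalized counts. Among genes of the acetylcholine receptor and synapse 5 of 11 measured members fell and 0 rose (camera adjusted p = 0.000944, and adjusted p = 0.0573 with an estimated correlation), with Rapsn from 4176 ± 286 to 1773 ± 364 and Musk from 7116 ± 380.5 to 4059 ± 1138. In the insulin-like growth factor axis 7 members rose and 5 of 13 fell (camera adjusted p = 0.89, and adjusted p = 0.889 with an estimated correlation). Igf1 fell from 2649.8 ± 541 to 858 ± 208 and the binding protein gene Igfbp5 from 25757 ± 3703 to 5993 ± 919, while Igfbp3 and Igfbp6 rose by 1.56 and 2.01 and the insulin receptor gene Insr by 1.22 on the log2 scale.

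The ketone libraries were more spread than the PBS libraries. The median SD of a gene on the log2 scale was 0.40 in ketone and 0.20 in PBS, and the first principal component (47.4% of the variance) separated the groups while the second (17.9%) set ketone library 2 at -77.2 against 49.7 for ketone library 1.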
